A study of Mus musculus with 24 samples.

How the data were processed

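Hippocampal RNA of C57BL/6 mice was sequenced in 24 libraries that fall into 4 groups by genotype and stress: 7 WT control, 6 WT stress, 6 KO control and 5 KO stress libraries. Per the labels' protocols, the tissue was micro-dissected and frozen, RNA was isolated with Tri-Reagent, and a service provider made the libraries and ran them on an Illumina instrument. The labels do not state how the libraries were selected for or depleted of ribosomal RNA, whether the mice were perfused, or the time of day at which tissue was taken. Groups and replicate numbers were taken from the sample titles, and every column of sample values in the tables was matched to 1 title.

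Read counts per gene symbol were deposited by the authors as whole numbers for each library, with no normalization. Per the submitters' processing notes, STAR, DESeq2 and the mouse genome build mm10 were used, with no versions or roles stated. The read counter, its annotation, its use of strand and its handling of reads shared between copies are not given in the sources used here. In each library 70.9% to 75.8% of the counts from 1 to 10 were even, so the mates of a pair appear to have been counted separately, and a fragment then weighs as 2 reads. The authors also deposited a table of normalized counts (unit: signal), in which each count is divided by 1 factor per library, and their table of 1 comparison gives the mean of these normalized counts over the 24 libraries, also a signal. Per the file headers, the authors' deposited table of 1 comparison further gives log2 fold changes with their standard errors. The score in that deposited table is the Wald statistic, and its p-value columns, per the file headers, are the p-value and the adjusted p of the authors' test. The groups compared are not named there, so that table was only set beside the tests made here, and all tests were made from the counts.

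Depth ran from 25711872 to 35148198 counts per library, and 17649 to 18326 genes had a count in a library. A gene with 3 reads in a library stood at 0.0854 to 0.117 CPM, and such a floor covers counting error only, since reads were not counted by unique molecule. The 10 most abundant genes took 3.43% to 7.78% of the counts. The table listed 24062 genes, of which 3153 had no count in any library, and 16313 were kept by the edgeR filter for low expression (minimum count 10) and tested. No pair of libraries agreed within sampling noise: the smallest mean chi-square per gene was 5.99 over all pairs and 9.35 within groups. The correlation of log2 CPM within groups was 0.961 to 0.987.

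Genes were tested with the quasi-likelihood F test of edgeR (robust fit, TMM factors) in 1 fit of 4 group means over all 24 libraries, with 20 residual degrees of freedom, a common dispersion of 0.0478 and a biological coefficient of variation of 0.219. The comparisons were stress against control in WT and in KO mice, the interaction (the KO stress effect minus the WT stress effect), KO against WT in controls and under stress, and both averages. Benjamini-Hochberg adjustment ran over the 16313 genes of each comparison, with a threshold of 0.05. CPM values of named genes use TMM-scaled library sizes, while CPM values of library properties such as Rn45s are over all reads. Il1r1 was also tested alone with an exact two-sided permutation test of log2(CPM + 0.5).

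The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Of 35 gene lists of pathways, brain regions and cell types, 34 had at least 5 measured members and were tested. The list of mitochondrially encoded genes had 0 of 26 members in the tested genes and was not. Lists were tested with camera of limma on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Beside the members that passed over all genes, each count was also adjusted over the list alone.

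The rule for named genes had 4 parts for each comparison except the averages. Il1r1, Il1b, Fkbp5 and Fos were always given. Among genes past the threshold with a mean of at least 1 CPM in a compared group and the same direction whichever library was left out, the 10 with the largest and the 10 with the smallest log2 fold change were taken. For each list up to 4 members past the threshold were taken, or, for a list called without one, its 2 members with the smallest p as values. Where fewer than 10 genes passed, all of them were taken, with those of the smallest p up to 10 in all as values, and the text names at most about 30 genes per comparison. Some genes that met the rule are not reported here. For the averages the rule allows counts and lists only, and genes named there were chosen after their values were seen.

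Alternatives fixed beforehand were RLE size factors, the DESeq2 Wald test, limma voom with quality weights, no expression filter, a stricter filter (1 CPM in 5 libraries), only the 2 groups compared, the replicate number as a block, a choroid plexus covariate, 1 surrogate variable, and each library left out in turn. Those chosen after seeing the data were a term for the library set, each set alone (from 1 fit of the groups within sets), a thalamus and habenula covariate, that covariate with the set term, the set 2 libraries with thalamic transcripts left out, and Rn45s left out. Library sets were parted at the largest gap in Rn45s, with a boundary of 14593 CPM. The first principal component held 29.99% of the variance and the next 10.3%.

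The edgeR test was tested on simulated data, in a simulated comparison of stress against control in WT mice over 16313 genes. It recovered 77.6% of 67 genes changed 1.5-fold, 86.6% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, and 9 of its 184 calls were false. The simulated counts were drawn independently around 1 mean per gene, with no library sets or tissue differences. Only genes with a mean of at least 1 CPM were changed. These shares therefore need not hold for the real libraries. Coordinates and gene identifiers are from the GENCODE annotation of mm10 (release M21), matched by symbol. Genes of families with near-identical copies (alpha- and beta-globin, Ctla2, Ly6, Ifitm, Serpina1, Mup, H2-K1 and H2-D1) share reads, and their counts are uncertain. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.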

Results

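RNA from the micro-dissected hippocampus of C57BL/6 mice was sequenced in 24 libraries that crossed genotype with social stress. The mice were wild type (WT) or lacked the interleukin-1 receptor 1 in neurons (knockout, KO), and either served as controls or went through social defeat by paired fighting, a stress built on aggressive encounters between mice. The WT control group had 7 libraries, WT stress 6, KO control 6 and KO stress 5. Total counts per library ran from 27533414 to 34741660 in WT controls, 26157103 to 35148198 in WT stress, 25711872 to 30002237 in KO controls and 27367656 to 28700444 in KO stress. The labels do not state that each library came from a separate mouse, so the p-values measure only the spread between these samples, which may in part be technical. Adjusted p-values below are from the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment unless another test is named, and log2 fold changes carry a standard error (SE). This SE was derived as the size of the log2 fold change divided by the square root of the F statistic. It is approximate, above all for genes with few reads.

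The 45S ribosomal RNA precursor Rn45s parted the libraries into 2 sets: 11 libraries, called set 1, held 24238 to 50453 CPM (counts scaled to library size; median 35868), and 13 libraries, called set 2, held 4107 to 8786 CPM (median 5917). Set 1 held 3 WT control, 2 WT stress, 4 KO control and 2 KO stress libraries, and set 2 held 4, 4, 2 and 3. The labels do not name the sets, which were found in the counts, so counts of genes are also given within them. The sets do follow the replicate numbers of the titles, since set 1 held the lowest numbers of every group. These were WT control 1 to 3, WT stress 1 and 2, KO control 1 to 4 and KO stress 1 and 2. The non-coding RNA Malat1 had a median of 1315 CPM in set 1 and 606 CPM in set 2, and the mitochondrial leucyl-tRNA synthetase gene Lars2 had 1894 and 541 CPM. In a test of set 2 against set 1 over 16313 genes, 1826 genes were higher and 1559 were lower in set 2.

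Transcripts of neighbouring brain regions also differed from library to library. Tcf7l2, a transcription factor strongly expressed in the thalamus, had 26.3 to 61.0 CPM in set 1 and 5.57 to 116 CPM in set 2. Within set 2, WT stress replicate 5 and KO stress replicates 3 and 5 had Tcf7l2 at 111, 116 and 92.3 CPM, and their mean of the 20 thalamus and habenula markers was at least as high as the lowest in set 1. Ttr, the transthyretin transcript of the choroid plexus, ran from 6.86 to 2411 CPM. Spink8, a transcript of hippocampal pyramidal cells, had a median of 7.34 CPM in set 1 and 19.9 CPM in set 2.

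**Figure D1:**
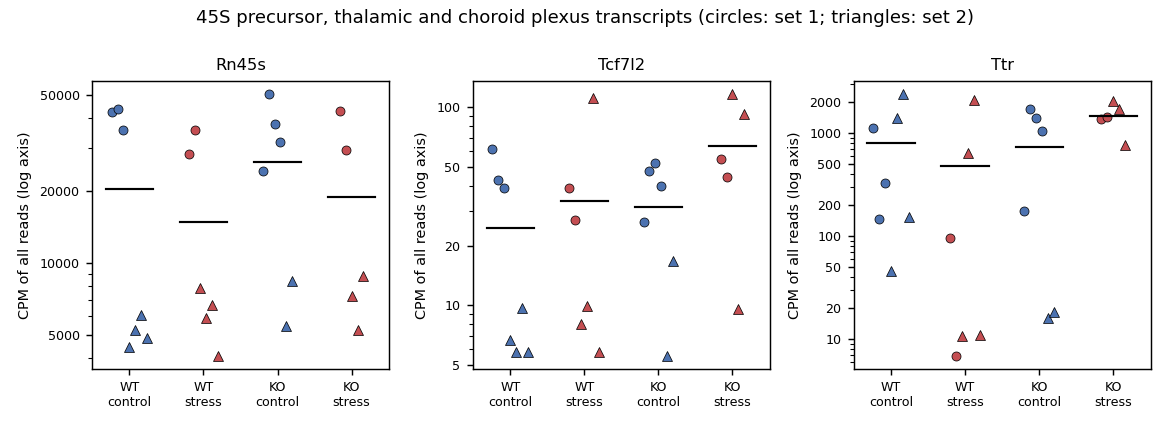
Rn45s (45S rRNA precursor), Tcf7l2 (thalamic marker) and Ttr (choroid plexus marker) in CPM on a log axis for each of the 24 libraries by group, with circles for set 1, triangles for set 2 and a line at the group mean. Set 1 libraries lie at 24238 CPM of Rn45s or above and set 2 libraries at 8786 CPM or below, while Tcf7l2 and Ttr vary within every group.

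Il1r1, the gene for the receptor that the knockout targets, was counted at similar levels in both genotypes. It lies on chromosome 1 from 40225080 to 40317257 on the plus strand (mm10; ENSMUSG00000026072.12, protein coding). Its mean was 3.35 ± 1.31 CPM in WT controls (SD, n = 7), 5.56 ± 1.45 in WT stress (n = 6), 3.44 ± 1.21 in KO controls (n = 6) and 5.54 ± 1.77 in KO stress (n = 5). The KO minus WT difference in log2 fold change was 0.04 ± 0.26 (SE) in controls (adjusted p = 1.0) and −0.0047 ± 0.27 under stress (adjusted p = 0.997). The exact two-sided permutation test gave p = 0.847 and p = 0.948 for these differences (0.948 and 0.948 after adjustment over the 4 comparisons of this gene). Because the deletion is confined to neurons by design and the gene is also expressed in brain endothelium, and because the labels do not say whether it removes counted exons, these levels do not settle the genotype labels.

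With stress, Il1r1 differed from controls by a log2 fold change of 0.73 ± 0.25 in WT mice (adjusted p = 0.684) and 0.69 ± 0.28 in KO mice (adjusted p = 0.988). The exact permutation test of this gene alone gave p = 0.0163 in WT and p = 0.0433 in KO mice, and 0.0653 and 0.0866 after adjustment over the 4 comparisons. Within set 1 the WT difference was 0.02 and the KO difference −0.07, and within set 2 they were 1.13 (adjusted p = 0.0536) and 1.51 (adjusted p = 0.265).

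**Figure D2:**
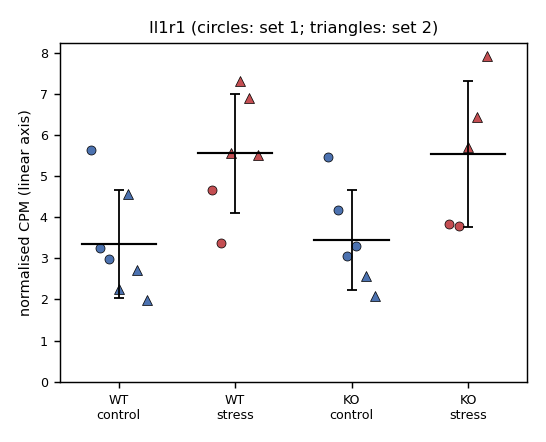
Il1r1 in CPM for each library in the 4 groups, with circles for set 1, triangles for set 2, and the group mean with bars of 1 SD. The group means were 3.35 and 5.56 CPM in WT control and stress libraries and 3.44 and 5.54 CPM in KO control and stress libraries.

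The effect of social defeat in WT mice was a rise of 22 of 16313 genes and a fall of 0 (WT stress, n = 6, against WT control, n = 7). At an unadjusted p under 0.05 in the edgeR test there were 720 genes, where chance gives 816. Lcn2, which encodes the iron-binding acute-phase protein lipocalin 2, rose 35.4-fold from 0.270 ± 0.243 to 9.73 ± 5.91 CPM (SD; log2 fold change 5.15 ± 0.75, adjusted p = 0.00180). S100a8 and S100a9, the subunits of the neutrophil protein calprotectin, rose 34.7-fold and 19.8-fold (adjusted p = 0.00536 and 0.00985). S100a8 and S100a9 had 25 and 58 reads in all over the WT controls, and Lcn2 had 57. The folds of S100a8, S100a9 and Lcn2 are therefore imprecise (SE of the log2 fold change 0.84, 0.75 and 0.75). Alas2, the erythroid enzyme that starts heme synthesis, rose 5.67-fold from 4.84 ± 1.33 to 27.4 ± 7.60 CPM (log2 fold change 2.50 ± 0.28, adjusted p = 9.62e-05). Genes of the vessel wall rose as well, among them Vwf, the von Willebrand factor gene, from 23.4 ± 4.81 to 57.6 ± 17.3 CPM (2.46-fold, adjusted p = 0.0154).

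Of the 6 measured red blood cell markers, 2 rose, Alas2 and the alpha-globin gene Hba-a2 (2.03 ± 0.872 to 8.65 ± 2.08 CPM, log2 fold change 2.09 ± 0.30, adjusted p = 0.00135), and 5 rose when adjusted over the list alone. Hba-a2 shares nearly all its sequence with Hba-a1 (log2 fold change 0.72 ± 0.65), so counts of this pair are uncertain. Of the 15 measured monocyte and neutrophil markers, 3 rose (S100a8, S100a9 and Retnlg) and all 15 did when adjusted over the list alone, with a median log2 fold change of 2.12. Both lists were called by camera with its preset correlation (adjusted p = 3.56e-17 and 1.99e-29) and with an estimated correlation (adjusted p = 0.000992 and 0.00223).

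Of the 19 measured cytokines, chemokines and adhesion genes, 2 rose, Lcn2 and Lrg1, a leucine-rich glycoprotein of inflamed endothelium (2.84 ± 1.10 to 10.7 ± 2.37 CPM, log2 fold change 1.91 ± 0.26, adjusted p = 0.000813). Adjusted over the list alone, 6 rose, with Icam1, Selp, Il4ra and Osmr as the others. Of the 22 endothelial markers, 2 rose, Vwf and Ly6a (25.4 ± 3.70 to 48.6 ± 6.77 CPM, adjusted p = 0.00356), 8 rose when adjusted over the list alone, and 21 had a log2 fold change above 0 (median 0.25). None of the 27 interferon-stimulated genes passed over all genes, with Ifitm3 at a log2 fold change of 0.85 ± 0.19 (adjusted p = 0.0900) and Isg15 at 0.82 ± 0.20 (adjusted p = 0.161). Of the 27, 10 rose when adjusted over the list alone and 26 lay above 0. These 3 lists were called with an estimated correlation too (adjusted p = 0.00234, 0.00234 and 0.00430), as were the 14 pericyte and smooth muscle markers (median 0.21, adjusted p = 0.0318). Of these 14, 0 passed and 3 rose when adjusted over the list alone, and the call of the list ended with the library set as a term (adjusted p = 0.0610 with an estimated correlation).

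The other genes that rose included Scgb3a1 (log2 fold change 3.14 ± 0.59), Tmem252 (2.20 ± 0.45), the exonuclease gene Isg20 (1.62 ± 0.28), Ctla2a (1.23 ± 0.17), Gm694 (1.06 ± 0.19), Ifitm1 (1.05 ± 0.21), Grrp1 (1.02 ± 0.16) and the early response gene Ier3 (0.98 ± 0.16). Smaller rises were found for the ubiquitin-conjugating enzyme gene Ube2l6 (0.87 ± 0.14), Igfbp7 (0.55 ± 0.10), Tmem176a (0.52 ± 0.09) and Anxa2 (0.44 ± 0.08). Their adjusted p-values ran from 0.000813 (Ctla2a) to 0.0427 (Tmem252). Apol11b, which lies outside the rule for named genes and was named after its values were seen, was the remaining gene. Ctla2a, Ly6a and the Ifitm genes belong to families of near-identical copies, and their counts are uncertain to that extent.

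Il1b, the gene for the receptor's ligand interleukin-1 beta, stood at 0.178 ± 0.0909 CPM in WT controls and 0.635 ± 0.374 CPM in WT stress (log2 fold change 1.81 ± 0.56, adjusted p = 0.467). Fkbp5, a glucocorticoid-induced gene, had a log2 fold change of −0.38 ± 0.20 and the immediate early gene Fos of 0.64 ± 0.53 (adjusted p = 1.0 for each). Fos had 0.23 without WT stress replicate 3 and 1.17 without WT control replicate 7. The 26 glucocorticoid-responsive genes were not called (preset adjusted p = 0.291), and 0 of them passed. Of the 23 genes of IL-1 receptor signalling 0 passed, with a preset adjusted p of 0.0367 that became an adjusted p of 0.421 with an estimated correlation. The same loss was seen for 8 further lists, among them the 23 microglia markers, of which 0 passed and 4 rose when adjusted over the list alone (C1qa, C1qb, C1qc and Ctss). Immediate early genes (Klf4 0.59, Sik1 0.57; 0.32 and 0.33 without WT stress replicate 3), microglia, perivascular macrophage, respiratory chain and cytosolic ribosomal protein genes had a direction above 0, and CA1 and CA3 pyramidal (Gpr161 −0.70, Grik4 −0.31), choroid plexus and ependymal markers below 0. Their adjusted p with an estimated correlation was 0.581, 0.421, 0.421, 0.591, 0.505, 0.581, 0.542 and 0.505 in that order. The median of the 21 choroid plexus markers was −0.48, and that of the 20 thalamus and habenula markers, not called, was 0.44.

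The rise held by direction within both library sets for the leading genes. Alas2 had a log2 fold change of 2.13 in set 1 (adjusted p = 0.258) and 2.70 in set 2 (adjusted p = 0.000646), and Lcn2 5.36 (adjusted p = 0.304) and 4.98 (adjusted p = 0.0146). S100a8 had 2.44 and 6.12, Lrg1 1.10 and 2.51, and Vwf 0.66 and 1.54. Set 1 alone, with 2 stress against 3 control libraries, gave 0 genes in the edgeR test (1599 of 17006 had an unadjusted p under 0.05), and set 2 alone gave 62, of which 18 were among the 22. The DESeq2 test called 61 genes (56 higher, 5 lower). Of the lower ones, Serpina3k, Mup3 and Mug1 had at least 10 reads in only 3 libraries. With the library set as a term 26 genes passed, 21 of them among the 22. The libraries in doubt, the 3 of set 2 with thalamic transcripts, left 15 genes when taken out, all among the 22.

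Of the 22 genes, 13 passed whichever of the 24 libraries was left out. Vwf did not pass without WT control replicate 1, 4 or 5 or WT stress replicate 3, 4 or 5 (adjusted p up to 0.0644). Ifitm1 did not pass without WT control replicate 1, 4, 5, 6 or 7 or WT stress replicate 3, 4, 5 or 6 (up to 0.112). Anxa2 did not pass without WT control replicate 1, 4 or 5 or WT stress replicate 4 or 5 (up to 0.0936), and Igfbp7 without WT control replicate 1 or WT stress replicate 3 or 4 (up to 0.0675). Scgb3a1 did not pass without WT control replicate 5 or WT stress replicate 3 (up to 0.0673) and Tmem176a without WT stress replicate 5 (0.0531). Tmem252 was lost without any 1 of 15 libraries of all 4 groups (up to 0.155, without WT stress replicate 6), and Retnlg and Apol11b also rested on single libraries. The count ranged from 15 genes, without WT control replicate 1 or 5 or WT stress replicate 4 or 5, to 27 without WT stress replicate 2.

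**Figure D3:**
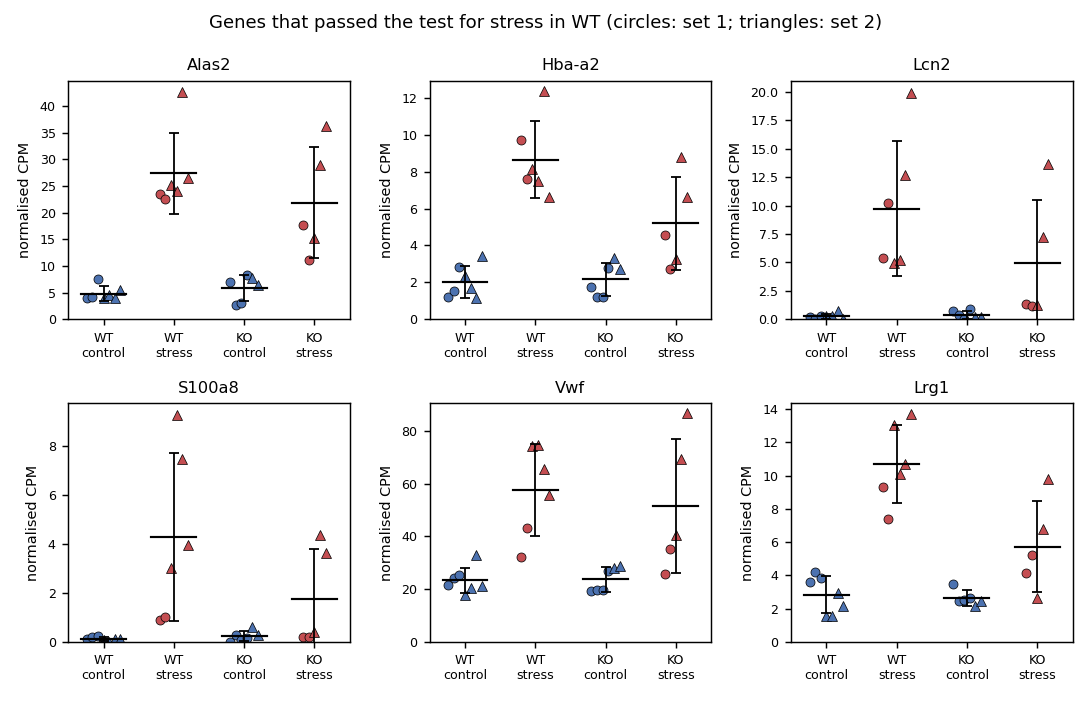
Alas2, Hba-a2, Lcn2, S100a8, Vwf and Lrg1 in CPM for each library in the 4 groups (blue, control; red, stress), with circles for set 1, triangles for set 2, a line at the group mean and bars of 1 SD drawn down to 0 at most. For Alas2 all 11 stress libraries (11.2 to 42.7 CPM) lie above all 13 control libraries (2.78 to 8.399 CPM), and for Lcn2 likewise (1.21 to 19.9 CPM against 0 to 0.945 CPM).

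In mm10, Alas2 (ENSMUSG00000025270.13) lies on chromosome X from 150547375 to 150570638 on the plus strand, and Lcn2 (ENSMUSG00000026822.14) on chromosome 2 from 32384633 to 32388252 on the minus strand. S100a8 (ENSMUSG00000056054.9) and S100a9 (ENSMUSG00000056071.12) lie close together on chromosome 3, from 90668978 to 90670035 and from 90692632 to 90695721. Hba-a2 (ENSMUSG00000069917.7) lies on chromosome 11 from 32296489 to 32297298, Vwf (ENSMUSG00000001930.17) on chromosome 6 from 125546774 to 125686679, and Lrg1 (ENSMUSG00000037095.8) on chromosome 17 from 56119678 to 56122001.

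In KO mice, social defeat raised Alas2 3.72-fold, from 5.88 ± 2.40 CPM in controls (SD, n = 6) to 21.9 ± 10.4 CPM under stress (n = 5; log2 fold change 1.90 ± 0.30, adjusted p = 0.0293). It was the 1 gene of 16313 that passed, with 0 lower. Members of the cytokine, myeloid and endothelial lists had values that did not pass: Lcn2 at 0.411 ± 0.353 and 4.96 ± 5.51 CPM (log2 fold change 3.60 ± 0.76, adjusted p = 0.331), the haptoglobin gene Hp (2.95 ± 0.66, adjusted p = 0.449), Vwf (1.12 ± 0.26, adjusted p = 0.577), Lrg1 (1.12 ± 0.28, adjusted p = 0.890) and S100a8 (2.90 ± 0.84, adjusted p = 0.988). The DESeq2 test called Hp (adjusted p = 0.00904), Vwf (0.0107) and Lcn2 (0.0223). The log2 fold change of Hp was 1.64 without KO stress replicate 1. That of Lcn2 was 2.76 without replicate 5 and that of S100a8 2.23 without replicate 4. Il1b stood at 0.177 ± 0.121 CPM in controls and 0.365 ± 0.334 CPM under stress (log2 fold change 1.02 ± 0.64), Fkbp5 at a log2 fold change of −0.053 ± 0.22 and Fos at −0.43 ± 0.58 (adjusted p of at least 0.988 for each). Without KO stress replicate 4 Il1b had 0.41, and without KO control replicate 5 Fos had −0.12.

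The 6 red blood cell markers were the 1 list of 34 called in KO mice with an estimated correlation (median log2 fold change 1.58, adjusted p = 0.00506). Of them 1 rose over all genes and 5 when adjusted over the list alone, among them Alas2, Hba-a2, Slc4a1 and Bpgm. Adjusted over the list alone, 5 of the 15 monocyte and neutrophil markers rose (S100a8, S100a9, Lyz2, Chil3 and Hp), 2 of the 19 cytokines, chemokines and adhesion genes (Lcn2 and Lrg1) and 1 of the 22 endothelial markers (Vwf), and over all genes 0 of each passed. The preset correlation called 18 lists. With an estimated correlation the adjusted p was 0.188 for the monocyte and neutrophil, 0.0873 for the endothelial, 0.272 for the interferon-stimulated (Ifitm3 0.51, Rsad2 0.84) and 0.375 for the cytokine list.

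The other lists called with the preset correlation lay on both sides of 0, as values. The 18 GABAergic interneuron markers had a median of −0.17 (Npy −0.47, Lhx6 −0.25; adjusted p = 0.0791 with an estimated correlation, and 0.286 without the KO stress replicates 3 and 5 and the WT library with thalamic transcripts), and the 30 immediate early genes one of −0.45 (Egr3 −0.69, Ier5 −0.56; adjusted p = 0.552). Without KO stress replicate 5 Npy had −0.29, and without replicate 3 Lhx6 had −0.14. The 21 choroid plexus markers had a median of 0.79 (Sostdc1 1.07, Slc13a4 0.46), the 13 ependymal markers 0.45 (Foxj1 0.69) and the 20 thalamus and habenula markers 0.51, with adjusted p = 0.375, 0.382 and 0.584. Oligodendrocyte and myelin markers (Fa2h 0.39, Trf 0.37), IL-1 receptor signalling (Irak4 0.59, Il18 −0.22), pericyte and smooth muscle (Kcnj8 0.40, Abcc9 0.55), fibroblast and meningeal (Cdh1 0.80, Bgn 0.26) and CA2 markers (Amigo2 0.36, Map3k15 0.50) had adjusted p = 0.669, 0.375, 0.375, 0.700 and 0.375. Neocortex, striatum and respiratory chain lists, with medians below 0, had adjusted p = 0.338, 0.700 and 0.700.

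The Alas2 call in KO mice did not hold in every fit, with a log2 fold change between 1.45 and 2.05 throughout. Its adjusted p was 0.0682 with the library set as a term (log2 fold change 1.79), 1.0 within set 1 (1.45), 0.283 within set 2 (1.92), and 0.177 without the 3 libraries of set 2 with thalamic transcripts (1.71). It was also lost without KO control replicate 1 (adjusted p = 0.0754), 2 (0.0870), 3 (0.105) or 6 (0.0996), KO stress replicate 4 (0.0952) or 5 (0.180), or WT control replicate 1 (0.0512) or 5 (0.0506). The DESeq2 test called 12 genes, among them Mup13, Gh, Serpina3k, Mug1 and Gm2083, which had at least 10 reads in no more than 3 libraries. In the edgeR test 648 genes had an unadjusted p under 0.05 where chance gives 816. The WT comparison, with 720, was also under that number.

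The 22 genes that rose in WT mice, chosen by that call, were set beside the stress effect in KO mice. All 22 had a log2 fold change above 0 in KO mice, 19 of them with an unadjusted p under 0.05, and their median was 1.46 in WT and 1.12 in KO mice. The list of calls shared 1 gene, Alas2. Among genes with an unadjusted p under 0.05, 89 were higher with stress in both genotypes where independent lists of 485 and 369 genes give 10.97 (Fisher's exact test, p = 5.02e-56), and 15 were lower in both where 4.02 are given by independence (p = 1.33e-05). Genes are not independent replicates, so these p-values overstate the evidence. The 3 libraries of set 2 with thalamic transcripts are all stress libraries, of both genotypes, and the overlap was not recomputed without them. Across all 16313 genes the log2 fold changes correlated with Pearson's r = 0.164 and Spearman's rho = 0.0897, and the 2 comparisons share no library. Within set 1 Pearson's r was −0.297 and within set 2 it was 0.387, and without WT stress replicate 5 it was −0.0855. Pearson's r was −0.281 without the 3 libraries of set 2 with thalamic transcripts, −0.203 from DESeq2 fold changes and −0.0860 with no expression filter. Spearman's rho was above 0 in these fits, at 0.108 within set 1, 0.391 within set 2, 0.0370 without the 3 thalamic libraries, 0.0463 from DESeq2 and 0.0456 with no filter.

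Whether the stress effect differed between genotypes was tested as the interaction, the KO effect minus the WT effect. Of 16313 genes 0 passed, 384 had an unadjusted p under 0.05 where chance gives 816, and DESeq2 called 4. The interaction was −0.61 ± 0.40 for Alas2, −1.55 ± 1.06 for Lcn2, −0.79 ± 0.38 for Lrg1 and −0.18 ± 0.35 for Vwf, −0.05 ± 0.37 for Il1r1, −0.79 ± 0.86 for Il1b, 0.33 ± 0.29 for Fkbp5 and −1.07 ± 0.78 for Fos (adjusted p = 1.0 for each). Over the 22 genes that rose in WT mice, chosen after their values were seen, all 22 had a smaller effect in KO mice (median −0.69), and 7 had an unadjusted p under 0.05. The smallest p adjusted over these 22 was 0.0600, shared by Gm694 (−0.92), Ctla2a (−0.72) and Ly6a (−0.65). Genes picked for passing in WT mice are by that choice set toward a smaller effect in KO mice.

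The interaction values with the smallest p included Serpina1a (8.09 ± 2.30), Serpina1c (7.85 ± 2.22) and Serpina1d (7.60 ± 2.04), near-identical copies of the liver alpha-1-antitrypsin gene, then Spef2 (2.70 ± 0.77), Cndp1 (2.15 ± 0.61) and the inhibin gene Inha (−0.46 ± 0.13), with adjusted p = 1.0 for each. Without KO stress replicate 1 the Serpina1a, Serpina1c and Serpina1d values were 6.11, 5.33 and 5.30, and without WT stress replicate 6 they were 11.69, 9.46 and 8.43. With the preset correlation 10 of 34 lists were called and with an estimated correlation 0 were, the smallest adjusted p being 0.517. As values, the choroid plexus markers had a median interaction of 1.39, the ependymal markers 0.68, the monocyte and neutrophil markers −1.001 and the immediate early genes −0.61.

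The genotype comparison in control mice asked what the loss of the neuronal receptor changed without stress. Hypothalamic neuropeptide genes had higher means in KO controls, as values that did not pass: Avp (vasopressin) had 0.360 ± 0.395 CPM in WT controls (SD, n = 7) and 36.2 ± 44.2 CPM in KO controls (n = 6), Oxt (oxytocin) 0.127 ± 0.125 and 20.3 ± 27.1 CPM, and Hcrt (hypocretin) 0.171 ± 0.116 and 18.1 ± 19.9 CPM. Their log2 fold changes were 6.60 ± 1.5, 7.22 ± 1.68 and 6.68 ± 1.70 (adjusted p = 1.0 for each), and within set 2 Avp had −0.36 and Hcrt −0.09. The higher means came from KO control replicates 2, 3 and 4, all of set 1, where Avp had 33.8 to 91.1 CPM over all reads. In KO control replicates 1, 5 and 6 Avp had 0.133 to 0.622 CPM, and Oxt and Hcrt were under 1 CPM there as well. These means therefore do not show a change shared by the KO controls. Of 16313 genes 0 passed, 493 had an unadjusted p under 0.05 where chance gives 816, and DESeq2 called 8.

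Further control values by p were Prph2 (3.34 ± 0.88), Vax1 (1.41 ± 0.39), Abi3bp (0.90 ± 0.24), Prr22 (0.62 ± 0.16), Gmnn (0.61 ± 0.17), Clrn1 (−1.26 ± 0.34) and A630072M18Rik (−0.35 ± 0.09). The 14 striatum markers had a median log2 fold change of 1.01 (Adora2a 1.91 ± 0.64, Rgs9 1.0 ± 0.33); 0 passed over all genes and 9 were higher when adjusted over the list alone, with adjusted p = 0.807 for the list with an estimated correlation. Within set 2 Adora2a had −0.92 and Rgs9 −0.05. The preset correlation called 7 lists and an estimated correlation 0. The 20 thalamus and habenula markers (Ramp3 1.19, Lrrc55 0.47), 23 oligodendrocyte and myelin markers (Mog 0.35), 15 neocortex markers (Rorb 0.53, Endou 0.85) and 27 interferon-stimulated genes (Irf9 0.31, Rsad2 0.73) had medians of 0.62, 0.24, 0.16 and 0.12. The 17 CA1 and CA3 pyramidal markers (Gpr161 −0.56, Coch 0.69) and 16 dentate granule cell markers (Il16 −0.64, Tdo2 −0.80) had medians of −0.31 and −0.29. Adjusted p with an estimated correlation was 0.929 for the myelin and dentate lists and 0.807 for the other 4. Il1b, Fkbp5 and Fos differed by −0.02 ± 0.62, −0.27 ± 0.20 and 0.33 ± 0.53.

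Genes beside the targeted locus and beside Slc17a6, whose promoter is used in some mouse lines to drive recombination in excitatory neurons, were examined because flanking sequence of another strain can travel with an altered locus. The 26 measured genes beside Il1r1 had a median log2 fold change of −0.05 in controls (preset adjusted p = 0.0915) and the 19 beside Slc17a6 one of 0.01 (preset adjusted p = 0.883), and 0 of either passed.

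Under stress, KO mice had a lower mean of the inflammation gene Lrg1 than WT mice, 5.71 ± 2.74 CPM (SD, n = 5) against 10.7 ± 2.37 CPM (n = 6; log2 fold change −0.91 ± 0.28), as a value that did not pass (adjusted p = 0.798). The complement genes C1qa and C1qc had log2 fold changes of −0.34 ± 0.13 and −0.33 ± 0.12, and Fbln7 one of 0.88 ± 0.23, with the same adjusted p. Of 16313 genes 0 passed, 768 had an unadjusted p under 0.05 where chance gives 816, and DESeq2 called 3. Further values by p were Mb (1.70 ± 0.45) and Efcab6 (−0.71 ± 0.20), and Il1b, Fkbp5 and Fos differed by −0.81 ± 0.59, 0.06 ± 0.21 and −0.74 ± 0.58.

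With the preset correlation 11 lists differed between genotypes under stress and with an estimated correlation 0 did. The 21 choroid plexus markers (median 1.32; Sostdc1 1.41, Slco1a5 1.52) and the 13 ependymal markers (median 0.85; Ccdc153 1.12, Foxj1 0.76) were higher in KO stress in 21 of 21 and 13 of 13 members, 4 ependymal markers were higher when adjusted over the list alone, and the adjusted p was 0.395 for both lists. The choroid plexus transcript Ttr had 769 to 2048 CPM in KO stress libraries and 6.86 to 2128 CPM in WT stress libraries. Markers of 1 tissue can vary together between libraries, so the counts of members are not separate evidence. The thalamus and habenula (0.82; Plekhg1 1.08, Adarb1 0.61), striatum (0.58; Adora2a 1.60, Penk 0.89) and myelin lists (0.36; Ermn 0.55) had medians above 0, with adjusted p = 0.526, 0.675 and 0.526. Medians below 0 were those of the monocyte and neutrophil markers (−0.56; Retnlg −1.77, S100a8 −1.28), cytokines (−0.20; Osmr −0.40), microglia (−0.13), immediate early genes (−0.42; Nr4a1 −0.94, Gadd45b −0.64), respiratory chain (−0.17; Uqcrb −0.20, Ndufa5 −0.24) and cytosolic ribosomal proteins (−0.17; Rps21 −0.38, Rps13 −0.21), with adjusted p = 0.526, 0.395, 0.675, 0.616, 0.616 and 0.616.

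Averaged over both genotypes, stress raised 34 of 16313 genes and lowered 1. Beyond the genes of the WT comparison, and named after their values were seen, the erythroid anion exchanger gene Slc4a1 (log2 fold change 3.54 ± 0.54, adjusted p = 0.00138) rose. So did Chil3 (3.98 ± 0.70), Hp (2.42 ± 0.44) and Lyz2 (1.13 ± 0.21) of the monocyte and neutrophil list. In KO mice the log2 fold change of Hp fell from 2.95 to 1.64 without KO stress replicate 1, where the liver gene Alb reached 53.7 CPM. The average call of Hp was kept without that library. The gene that fell was Arntl, a core activator of the circadian clock (−0.26 ± 0.05, adjusted p = 0.0253). Over all genes 6 of the 15 monocyte and neutrophil markers, 4 of the 6 red blood cell markers, 2 of the 22 endothelial markers and 1 of the 27 interferon-stimulated genes rose, and 15, 5, 11 and 14 did when adjusted over the list alone. The same 2 counts were 1 and 3 of the 14 pericyte and smooth muscle markers. With an estimated correlation 7 lists were called: these 4 (adjusted p = 0.00234, 0.000282, 0.00229 and 0.00601), cytokines (0.00846), pericyte and smooth muscle markers (0.0246) and, below 0, GABAergic interneuron markers (median −0.14, adjusted p = 0.0177), of which 0 passed. The 3 libraries of set 2 with thalamic transcripts are all stress libraries, and without them the adjusted p with an estimated correlation was 0.179 for the GABAergic interneuron markers and 0.143 for the pericyte and smooth muscle markers. The pericyte and smooth muscle markers also had 0.0866 with the library set as a term and 0.0516 with the thalamic covariate.

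The average stress count differed between library sets and tests. It was 0 genes within set 1 (1142 of 17006 with an unadjusted p under 0.05), 131 within set 2, 77 with DESeq2 (72 higher, 5 lower) and 20 without the 3 libraries of set 2 with thalamic transcripts, 19 of them among the 35. Arntl did not pass with the replicate number as a block (adjusted p = 0.0952, log2 fold change −0.255), with the library set and thalamic covariate together (0.155, −0.213), within set 1 (0.700, −0.216) or without the 3 thalamic libraries (0.395, −0.200). It also did not pass without KO control replicate 6 (28 genes in all) or KO stress replicate 3 (32), 4 (26) or 5 (28).

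Averaged over control and stress, 0 of 16313 genes differed between genotypes, 945 had an unadjusted p under 0.05 where chance gives 816, and DESeq2 called 4. The interaction and the genotype comparisons in controls, under stress and on average also gave 0 genes within set 1 (605, 996, 684 and 942 of 17006 with an unadjusted p under 0.05) and within set 2 (544, 360, 1355 and 861). Among lists, 10 of the 20 thalamus and habenula markers and 10 of the 14 striatum markers were higher in KO mice when adjusted over the list alone, with medians of 0.74 and 0.81, and 0 of 34 lists were called with an estimated correlation (adjusted p = 0.570 for both). Genes beside Il1r1 and beside Slc17a6 had preset adjusted p = 0.0895 and 0.431. Without WT stress replicate 5 the count was 4, and the 4 genes were Avp, Hcrt, Oxt and Pmch, named after their values were seen.

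The authors' deposited table of 1 comparison, whose groups it does not name, listed 104 of 17705 genes past an adjusted p of 0.05, 99 higher and 5 lower. In the authors' deposited table Alas2 had a log2 fold change of 2.54 and Lcn2 of 5.31. Its fold changes correlated across 16313 genes with those of stress in WT mice at r = 0.918, with the average stress effect at 0.745 and with stress in KO mice at 0.215. All 22 genes that rose in WT mice here were among the calls of the authors' deposited table.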

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

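The tests of the hypothalamic pattern, and the list of hypothalamic genes behind them, were chosen only after the result was seen, while the outlier check and the list tests of the interaction were set beforehand.

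Single libraries stood far from the rest of their group for 18 of 440 combinations of a named gene and a group (110 genes), where chance gives about 22 at 1 in 20. WT stress replicate 5 was highest for Plekhg1 (60.1 CPM), Hcrt (25.7 CPM), Avp (10.8 CPM), Oxt (6.11 CPM) and Alas2 (42.7 CPM), and lowest for Efcab6 (5.402 CPM). WT stress replicate 6 was lowest for the myelin gene Mog (53.4 CPM) and highest for Serpina1a (0.264 CPM), and WT stress replicate 1 was lowest for Abcc9 (4.32 CPM) and Isg20 (1.32 CPM). WT control replicate 3 was highest for Inha (47.7 CPM) and Serpina1d (2.76 CPM). KO control replicate 1 was highest for Kcnj8 (5.77 CPM) and Clrn1 (0.702 CPM) and lowest for Cndp1 (0.0780 CPM). Among KO stress libraries, replicate 1 was highest for Map3k15 (2.53 CPM), replicate 2 lowest for Abcc9 (5.48 CPM) and replicate 4 lowest for Ramp3 (13.1 CPM).

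Stress effects differed between genotypes for 10 lists in camera with its preset correlation, and for 0 of 34 with an estimated correlation or with fry. The median interaction (KO effect minus WT effect, log2) was 1.39 for choroid plexus markers (preset adjusted p = 8.67e-14) and 0.68 for ependymal markers (4.39e-08). It was −1.001 for monocyte and neutrophil markers (preset adjusted p = 5.66e-05), −0.61 for immediate early genes (3.41e-07), −0.35 for cytokines, chemokines and adhesion genes (0.00205), −0.30 for neocortex markers (0.0317), −0.17 for respiratory chain genes (8.84e-10), −0.16 for ribosomal protein genes (8.84e-10), −0.14 for interferon-stimulated genes (0.0113) and −0.12 for circadian clock genes (0.00843). With an estimated correlation the adjusted p was 0.686 for the respiratory chain, ribosomal protein and interferon lists and 0.517 for the other 7.

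Some libraries, more of them KO, held transcripts of the hypothalamus: Pmch, the melanin-concentrating hormone gene of the lateral hypothalamus, picked after its values were seen, exceeded 10 CPM in 7 of 11 KO libraries and in WT stress replicate 5 alone of 13 WT libraries. No gene passed for genotype on average (0 of 16313 in edgeR, smallest adjusted p = 0.623, 945 with an unadjusted p under 0.05, and 4 called by DESeq2). The tables argue against the library set as the whole cause, since the genotype difference in the mean log2 CPM of 18 hypothalamic genes was 1.34 over all libraries, 1.85 within set 1 and 0.563 within set 2, so that the larger within-set difference was 1.38 times the overall one. Hypothalamic tissue in some dissected pieces is a candidate explanation that stays open: all 18 genes were higher in KO mice on average (median log2 fold change 1.69, fry p = 0.0124, permutation test of the list mean p = 0.0165). The list was written after hypothalamic transcripts had been seen in more KO than WT libraries. These p-values are therefore not separate evidence. For Pmch and Avp the values argue against genotype alone. KO control replicates 1, 5 and 6 and KO stress replicate 4 had 0.0697 to 0.272 CPM of Pmch and 0.133 to 1.10 CPM of Avp. WT stress replicate 5 had 52.2 and 11.4 CPM. An added effect of the genotype on the hypothalamic genes was not tested apart from tissue content and stays open. Of these 18 genes 4 had a median of at least 1 CPM in the 16 libraries with Pmch under 10 CPM, 0 are in another list, and 4 (Nr5a1, Fezf1, Pomc and Hdc) may have been seen in the data before the list was written, while the most abundant transcript, Avp, reached 91.1 CPM.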

How the results depend on the processing

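The library set, thalamic and Rn45s settings below, and every setting of the correlation between the stress effects other than RLE factors, the stricter filter and the block, were chosen only after the results were seen. Of the values of named genes other than those that leave out 1 library, 1223 under the planned settings kept their direction and their side of the threshold, 8 newly passed it, 17 no longer passed and 7 turned direction, and 947, 2, 36 and 30 did so under the added ones. Where a value changed, the cause was not tested, except that the sets alone and the libraries left out have fewer samples.

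The count of genes for stress in WT mice was 22, and it was 61 with DESeq2, 0 within set 1 and 62 within set 2, and 15 to 32 under the other settings. The KO count of 1 was 12 with DESeq2 and 0 with no expression filter, with only the 2 groups compared, with the choroid plexus covariate, with 1 surrogate variable, with the library set term, within set 1, within set 2, with the thalamus and habenula covariate, with the set term and that covariate, and with the set 2 libraries with thalamic transcripts left out. Arntl, the gene lower on average, was lost under the block (adjusted p = 0.0952), with a log2 fold change of −0.255 against −0.256 in the main fit. The count of 35 for stress on average was 77 with DESeq2, 56 with 1 surrogate variable, 0 within set 1, 131 within set 2 and 20 with the thalamic set 2 libraries left out. The edgeR count of 0 became 4 with DESeq2 for the interaction, 8 for genotype in controls, 3 for genotype under stress and 4 for genotype on average. These DESeq2 calls were genes with at least 10 reads in no more than 3 libraries (Serpina3k, Mug1, Mup3, Mup13, Gh and Gm2083) and the hypothalamic Avp, Hcrt, Oxt and Pomc. Genes of the first kind were also among the DESeq2 calls for stress in WT mice, in KO mice and on average.

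Without 1 library the count ran from 15 to 27 for stress in WT mice, 0 to 2 in KO mice, 26 to 48 on average, 0 to 4 for genotype on average (4 without WT stress replicate 5) and was 0 throughout for the other 3. The KO count was 2 without KO stress replicate 2, and 0 without KO control replicate 1, 2, 3 or 6, KO stress replicate 4 or 5, or WT control replicate 1 or 5. The log2 fold change of Il1r1 ran from 0.64 to 0.90 for stress in WT mice, 0.52 to 0.86 in KO mice, −0.22 to 0.13 for the interaction, −0.13 to 0.21 for genotype in controls and −0.17 to 0.10 under stress. Fkbp5 ran from −0.16 to 0.073 for stress in KO mice and −0.046 to 0.19 for genotype under stress, and Il1b from −0.33 to 0.24 for genotype in controls. Without 1 library, further values that did not pass moved by over 1.5 times. For the interaction Il1b ran from −1.40 to −0.48, Fkbp5 from 0.21 to 0.46 and Fos from −1.60 to −0.67. For genotype in controls Fkbp5 ran from −0.36 to −0.15, Fos from 0.024 to 0.86 and Rgs9 from 0.55 to 1.15. For genotype under stress Il1b ran from −1.42 to −0.54, Fos from −0.91 to −0.34, Nr4a1 from −1.18 to −0.56, S100a8 from −1.94 to −0.90, Sostdc1 from 1.12 to 2.15, Plekhg1 from 0.86 to 1.73 and Penk from 0.52 to 1.12.

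Lists called with the preset correlation numbered 15 for stress in WT mice and 6 with an estimated correlation or with fry. For stress in KO mice 18 became 1 with either and 10 with the choroid plexus covariate. For the interaction 10 became 0 with either, for genotype in controls 7 became 0 with either and 12 with the library set term, for genotype under stress 11 became 0, for stress on average 15 became 7 and was 9 with the thalamic set 2 libraries left out, and for genotype on average 12 became 0 and was 1 with the thalamic covariate.

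Directions that turned were all of values that had not passed the threshold. For stress in WT mice Fkbp5 was 0.019 within set 2, and Klf4 −0.14 and Sik1 −0.20 within set 1. For stress in KO mice, within set 1 Il1r1 was −0.067, Fa2h −0.078 and Trf −0.062. Fkbp5 there was 0.083 with the set term, 0.025 within set 1, 0.11 within set 2, 0.15 with the set term and thalamic covariate and 0.17 with the thalamic set 2 libraries left out, and Fos was 0.10 with the choroid plexus covariate, with 1 surrogate variable and with the thalamic covariate. Il1r1 was 0.38 for the interaction within set 2 and 0.079 for genotype under stress within set 2. For genotype in controls Il1r1 was −0.035 under the replicate block, −0.022 with 1 surrogate variable, −0.30 within set 2, −0.028 with the thalamic covariate and −0.011 with it and the set term. Il1b there was 0.072 with 1 surrogate variable, 0.054 with the set term, 0.81 within set 2, 0.10 with the thalamic covariate and 0.11 with it and the set term, and Fos was −0.051 within set 1. Within set 2 Gpr161 was 0.25, Mog −0.093, Rgs9 −0.051, Adora2a −0.92, Avp −0.36 and Hcrt −0.090. For genotype under stress Fkbp5 was −0.00638 with limma, −0.075 with 1 surrogate variable, −0.080 within set 2 and −0.045 with the thalamic covariate.

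The correlation of the stress effects of WT and KO mice (r = 0.164) was −0.297 within set 1, −0.281 with the thalamic set 2 libraries left out, −0.203 with DESeq2 and −0.0860 with no expression filter, and ran from −0.0855 (without WT stress replicate 5) to 0.218 without 1 library. Spearman's rho (0.0897) was above 0 in every planned and added setting (0.0160 to 0.391) other than those that leave out 1 library, where it was not computed.

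The replicate numbers shared by the groups did not pair the samples: same-numbered libraries deviated together (r over 0.1) in 4 of 6 pairs for WT stress against control, 1 of 5 for KO, 4 of 6 for the controls and 4 of 5 for stress, with a lowest r of −0.278. Libraries correlated best with their own number in 2 of 12, 0 of 10, 1 of 12 and 3 of 10 cases. In each group the lowest numbers were those of set 1, so most same-numbered libraries also shared a set. With the number as a block the count was 24 for stress in WT mice (18 of them among the 22), 1 in KO mice, 36 on average and 0 for the other comparisons. Depth limits genes near 3 reads, which is 0.0854 to 0.117 CPM, and in WT controls S100a8 (0.119 CPM), Scgb3a1 (0.148 CPM) and Il1b (0.178 CPM) stood close to that level.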

Other observations

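The tests of the blood and library set patterns were chosen only after the results were seen, the genes named in the first 2 paragraphs after their values were seen, and the counts of other splits of the samples were planned.

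Of the circadian clock genes, Arntl, an activator, fell with stress averaged over genotypes. It stood at 26.4 ± 1.48 CPM in WT controls (SD, n = 7) and 22.5 ± 2.36 in WT stress (n = 6), and at 24.5 ± 1.13 in KO controls (n = 6) and 20.2 ± 1.96 in KO stress (n = 5), with stress libraries from 18.2 to 24.8 CPM and controls from 22.5 to 28.4 CPM. The log2 fold change of Arntl was −0.26 ± 0.05 (edgeR adjusted p = 0.0253), but the call was lost with the replicate number as a block (0.0952, log2 fold change −0.255), with the library set and thalamic covariate together (0.155, −0.213) and within set 1 (0.700, −0.216). It was also lost without the 3 thalamic libraries of set 2 (0.395) and without KO control replicate 6 or KO stress replicate 3, 4 or 5 (0.0549 to 0.0738). Its partner Npas2 had a value of −0.25 ± 0.08 (adjusted p = 0.367 over all genes) and fell when adjusted over the list alone. Of the 17 measured clock genes 1 fell over all genes and 2 when adjusted over the list alone, with a median of 0.00 and a preset adjusted p of 0.919. The labels do not give the time of day at which tissue was taken.

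For stress on average, 0 of the 23 measured genes of the IL-1 pathway list passed over all genes in the edgeR test. Adjusted over the list alone, 4 rose (Il1b, Il1r1, Irak4 and Nfkb1), and 19 had a log2 fold change above 0 (median 0.08). The list was called with the preset correlation (adjusted p = 0.00478) and not with an estimated one (adjusted p = 0.210). Of the 18 GABAergic interneuron markers 2 lay above 0 on average, and those below included Npy (−0.30 ± 0.15), Dlx6os1 (−0.23 ± 0.12), Lhx6 (−0.19 ± 0.09) and Gad1 (−0.09 ± 0.06), none of which passed (adjusted p = 0.824 to 0.909). The GABAergic interneuron markers as a list were not called without the 3 thalamic libraries of set 2, all stress libraries (adjusted p = 0.179 with an estimated correlation). Transcripts of other organs were present in single libraries. Gh and Prl, the growth hormone and prolactin genes of the pituitary, reached 29.98 and 11.6 CPM in KO stress replicate 3 and 39.1 and 5.45 CPM in KO stress replicate 5. Alb, the albumin gene of the liver, reached 53.7 CPM in KO stress replicate 1, 24.1 CPM in WT control replicate 3 and 7.88 CPM in WT control replicate 4.

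Red blood cell and neutrophil transcripts rose with stress together. In WT mice the mean of all 21 red blood cell and myeloid members rose by 1.90 on the log2 scale, and that of the 22 endothelial members by 0.30. The difference was 1.59 (exact two-sided permutation p = 0.000583), with 0.88 in set 1 and 1.94 in set 2. The pattern was picked because these lists rose in the same libraries, so this p is not separate evidence. The values argue against more blood vessel as the whole cause only as far as the 22 endothelial markers track vessel content. Vessels that these markers count poorly were not tested. The tables also argue against the library set, since 21 of the 22 genes passed with the set as a term. More blood left in the tissue of stressed mice may account for part of the rise: over 24 libraries, with group means removed, the means of the red blood cell and the monocyte and neutrophil lists correlated at Pearson's r = 0.848 (95% interval 0.657 to 0.937) and Spearman's rho = 0.858 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give), at r = 0.816 without KO stress replicates 2 and 4, and at 0.805 in set 1 (n = 11) and 0.807 in set 2 (n = 13). In control libraries 3 of the 6 red blood cell and 5 of the 15 myeloid genes had a median of at least 1 CPM, 0 are in another list, and the most abundant transcripts of red blood cells cannot be used, since Hbb-bs had 0 to 7 reads per library, Hbb-bt 0 and Hba-a2 35 to 434, as happens where reads shared between near-identical copies are not assigned. A response of blood and vessel cells to the stress itself was not tested apart from blood content and stays open. Lcn2, Lrg1 and Ly6a also rose and lie outside the blood cell lists. The cells they came from were not determined, so these genes do not decide it.

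The 45S rRNA precursor Rn45s parted the libraries into sets of 11 and 13 that the labels do not name and that each hold libraries of all 4 groups. In every group the libraries of set 1 had the lowest replicate numbers in the titles. Thalamic tissue in the dissected piece was considered as the source. Among the 3 set 2 libraries with thalamic transcripts at the level of set 1 the highest Rn45s was 8786 CPM, where set 1 began at 24238 CPM. The sets were parted by Rn45s itself, so this outcome was fixed and does not decide the question. That such libraries exist shows only that high thalamic transcripts can occur without high Rn45s. A difference in RNA handling or library preparation is a candidate source that could not be tested. The labels give no batch and do not say what the replicate numbers stand for. No biological explanation was tested.

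Other splits of the libraries into groups of the same sizes, 100 for each comparison with the real one included, gave the following counts in the edgeR test. For stress in WT mice 4 of 100 splits gave at least the real 22 genes. The 100 were drawn from 1716 possible splits, so a share this near 0.05 does not exclude chance. The highest other split gave 786 genes, and 5 of the others gave any. For stress in KO mice 4 splits gave at least the real 1 gene, and the highest other, with 97 genes, was the split that follows the library sets exactly, while within set 1 and within set 2 the KO count was 0. For stress on average 1 split, the real one, gave 35 genes, and the highest other gave 1. The real count was 0 for the interaction, for genotype in controls, under stress and on average, where the comparison with other splits decides nothing, since all 100 splits give at least 0, with 2029, 2701, 587 and 948 genes in the highest other split. Beside these 0 counts 384, 493, 768 and 945 genes had an unadjusted p under 0.05 and DESeq2 called 4, 8, 3 and 4. Splits with many times the real count point to a structure of the samples, and the share of set 1 libraries differed between the groups of the highest such splits by 0.524 for WT stress, −1 for KO stress, 0.857 for genotype in controls, 0.497 for genotype on average, −0.25 for the interaction and 0.0667 for genotype under stress. In the real grouping it differed by −0.0952, −0.267, 0.238, 0.161, −0.0833 and 0.0667 in that order, so for genotype under stress the highest split parted the sets no more than the real grouping did. Within the sets the WT stress count was 0 in set 1 and 62 in set 2, and with the set as a term it was 26.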
